A study of Mus musculus with 2 samples.

How the data were processed

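N6-methyladenosine (m6A) is a methylated form of adenosine that occurs inside messenger RNAs. It was mapped by miCLIP, in which RNA fragments are crosslinked to an anti-m6A antibody and the crosslink leaves mutations or truncations in the cDNA that mark the methylated base. The RNA came from testes of control mice at 12 days post-partum. Per the labels' protocols, mRNA was isolated from the testes and the libraries were sequenced as paired reads. The 2 samples form 1 group, and the labels number them as replicates 1 and 2. The labels do not say whether the replicates came from separate animals, so any spread between them may be technical. The series text also names Mettl3 conditional knockout testes and expression measurements, which were not analysed here.

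Each deposited list gives the chromosome, start, end and strand of intervals of 5 nt, with 1 list per replicate. The name and score fields hold an asterisk on every line, so no read count, mutation rate or other strength came with a site, and the sequencing depth behind each site is unknown. Per the submitters' processing notes, the genome build was mm9 and the tools included CASAVA and BWA 0.7.10. The site caller, its thresholds and the filters are not given in the sources used here. These steps decide which sites enter a list: a site missing from a list may have failed a threshold or may have had no reads.

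Some positions stood on several lines of a list. A site was counted once per chromosome, start and strand, and the number of lines was kept as a separate property. Coordinates are given 1-based on mm9. A site was called shared when both replicates listed the same chromosome, start and strand. As a background for sharing, the sites of replicate 2 were moved along the chromosome by every offset from 20 to 500 nt in both directions, 962 offsets in all, and the matches were counted again, which keeps the local density of sites. Neighbours were counted within 100 nt and 1 kb on the same strand, with the opposite strand as a reference. Sites on 1 strand with gaps of at most 1 kb were joined into groups. Sites per Mb were taken over the span from the chromosome start to the last listed site, since chromosome lengths of mm9 were not used here. Shares carry 95% Wilson intervals. Intervals treat sites as independent and cover counting error only. Chromosome shares of the 2 replicates were compared with 2-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 22 tests. These tests compare 2 libraries, and shared sites enter both sides.

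Gene names, transcript regions, sequence motifs, distances to stop codons and coverage of the gene lists had been planned. They need an mm9 genome or annotation, which was not used here, and the table of gene symbols at hand describes another build, so no site was given a gene. The gene lists fixed for the work (spermatogonial, meiotic, m6A machinery, piRNA, chromatin, somatic cell, spermatid, histone, ribosomal, respiratory, early response and housekeeping genes) therefore have no result. Score agreement and a stricter score threshold were also planned and could not be computed, because the score field is empty. Under the rule set before the data were examined, with no gene names and no site values, the regions named are the 5 densest 1 kb windows of shared sites on 1 strand, each window starting at a shared site. Ties between windows were broken by the total number of sites in both replicates and then by coordinate, an order taken from the rule for genes. The closing part names other regions, which were chosen after their values were seen.

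The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The overlap code was tested on simulated lists of 7000 and 7200 sites in which 1700 positions were shared, and it recovered 1700. Alternatives to the matching distance, strand, merging of sites, neighbour window and set of sites were computed, as was each replicate without the other.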

Results

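Single-nucleotide m6A sites were mapped in testes of control mice on day 12 after birth, an age at which the first wave of germ cells has entered meiotic prophase. The design holds 1 group of 2 replicates, so the comparisons it allows are between replicates, between chromosomes and between positions. Replicate 1 held 7019 distinct sites on 7549 lines, and replicate 2 held 7182 distinct sites on 7697 lines. The mean was 7100.5 ± 115 sites (SD, n = 2). The read depth behind the lists is unknown. Both strands carried similar numbers of sites, with 50.7% of replicate 1 sites (95% Wilson interval 49.5 to 51.8%) and 52.1% of replicate 2 sites (50.9 to 53.2%) on the plus strand.

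The first comparison asked how m6A sites were spread over the chromosomes of testis. Chromosome 11 carried the largest number in both replicates, with 622 sites in replicate 1 and 621 in replicate 2, or 8.75% ± 0.152 of all sites (SD, n = 2). It also had the highest density among the autosomes and the X chromosome, at 5.12 ± 0.00582 sites per Mb. Chromosome 17 followed at 4.08 ± 0.163 and chromosome 19 at 3.997 ± 0.392 sites per Mb, which differed by less than the spread between replicates. Chromosome 7 had 3.45 ± 0.0279 and chromosome 9 had 3.49 ± 0.00573 sites per Mb. Among the autosomes, chromosome 14 had the lowest density, at 1.76 ± 0.0346 sites per Mb, and chromosome 3 the next lowest, at 1.94 ± 0.0404 sites per Mb.

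The X chromosome carried 223 sites in replicate 1 and 230 in replicate 2, a share of 3.19% ± 0.0179 (SD, n = 2). Its density of 1.37 ± 0.0299 sites per Mb was below that of each of the 19 autosomes in both replicates. The autosomes together held 2.76 sites per Mb in replicate 1 and 2.82 in replicate 2, so autosomal density was 2.04 ± 0.0114 times that of the X chromosome (n = 2). Densities per Mb do not correct for the number or the expression of genes on a chromosome. The Y chromosome had 3 sites in each replicate, and unplaced contigs had 12 in replicate 1 and 10 in replicate 2. The replicates did not differ detectably in the share of any chromosome: 0 of 22 Fisher's exact tests passed at an adjusted p of 0.05, 0 passed at an unadjusted p of 0.05, and the lowest unadjusted p was 0.198, for chromosome 19.

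**Figure D1:**
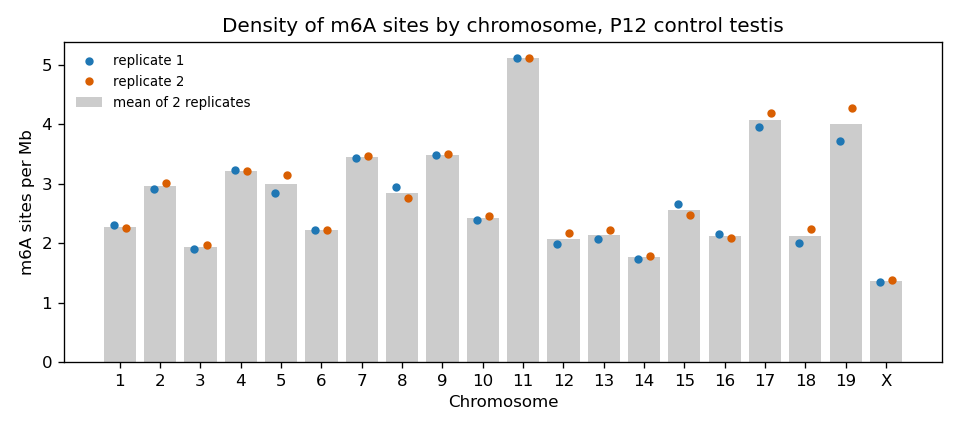
Density of m6A sites on each autosome and the X chromosome, in sites per Mb from the chromosome start to the last listed site; grey bars are means of 2 replicates and dots the single replicates. Chromosome 11 stands highest at 5.12 sites per Mb and the X chromosome lowest at 1.37.

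The replicates were then compared site by site. They shared 1685 positions, which was 24.0% of the sites of replicate 1 (23.02 to 25.02%), 23.5% of those of replicate 2 (22.5 to 24.5%) and 13.5% of the 12516 positions found in either. After replicate 2 was moved by fixed offsets, a mean of 2.36 positions matched, and the highest count over 962 offsets was 14. The observed overlap was therefore 120 times the highest offset count, while most of each list had no counterpart at the same position. The offsets keep the local density but not the set of positions that could be called. If only certain positions, such as those of a motif, could be called, low offset counts were fixed in advance. The ratio then does not measure the excess over a random draw from such positions. Of the X-linked sites of replicate 1, 18.8% were shared (14.2 to 24.5%), against 24.2% of its autosomal sites (23.2 to 25.2%; Fisher's exact test, 2-sided, p = 0.0671). In replicate 2 these shares were 18.3% and 23.6% (Fisher's exact test, 2-sided, p = 0.0684). Neither difference passed 0.05, and both rest on the same 42 shared X-linked sites.

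Sites without an exact match often lay close to sites of the other replicate. Of the unmatched sites of replicate 1, 34.0% had a replicate 2 site within 1 kb on the same strand (32.7 to 35.3%), and 0.787% had one on the opposite strand (0.583 to 1.06%). The unmatched sites of replicate 2 gave 31.9% (30.6 to 33.1%) and 0.655% (0.473 to 0.905%). Unmatched sites had a neighbour from their own replicate within 1 kb about as often, at 35.1% in replicate 1 (33.8 to 36.3%) and 32.2% in replicate 2 (30.9 to 33.4%).

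Within each replicate, sites had neighbours on the same strand far more often than on the opposite strand. A neighbour within 100 nt on the same strand was present for 15.1% of sites in replicate 1 (14.28 to 15.96%) and 12.7% in replicate 2 (11.9 to 13.5%). On the opposite strand the shares were 0.142% and 0.0557%. Within 1 kb, 34.8% and 33.0% of sites had a same-strand neighbour, and 0.841% and 0.585% an opposite-strand one. The opposite strand was the only reference. Sites confined to transcribed strands could give such an excess without clustering along a transcript, which was not tested. Among the 1685 shared sites alone, a smaller set in which only shared sites counted as neighbours, 7.48% had a same-strand neighbour within 100 nt and 14.6% within 1 kb. With every site of replicate 1 as a possible neighbour, 1112 of the 1685 shared sites had none within 1 kb, against 4576 of all 7019 sites. In replicate 2 these counts were 1084 of 1685 and 4813 of 7182. Among positions on 2 or more lines, the shares within 100 nt were 2.70% in replicate 1 and 1.72% in replicate 2, and within 1 kb they were 7.26% (35 of 482) and 2.15% (10 of 465). Here too only members of the smaller set counted as neighbours. With every site as a possible neighbour, 41.9% of the repeated positions of replicate 1 had one within 1 kb, against 34.3% of its positions on 1 line. In replicate 2 these shares were 36.3% and 32.8%. Joining sites with gaps of at most 1 kb gave 5558 groups in replicate 1 and 5800 in replicate 2, of which 82.3% and 83.0% held a single site. Groups of 5 or more sites numbered 41 in replicate 1 and 29 in replicate 2. Of the groups with more than 1 site, 68.6% in replicate 1 (65.7 to 71.5%) and 67.9% in replicate 2 (64.9 to 70.7%) had a same-strand site of the other replicate within 1 kb, against 39.0% (37.6 to 40.4%) and 37.2% (35.9 to 38.6%) of the single sites. A group with more sites has more chances of such a neighbour. At the level of exact positions, crowding made little difference in replicate 1, where 24.3% of sites with no neighbour within 1 kb were shared (23.1 to 25.6%) and 25.3% of those with 3 or more neighbours (21.5 to 29.5%). In replicate 2 these shares were 22.5% (21.4 to 23.7%) and 29.0% (24.3 to 34.2%), so there the crowded sites recurred more often and the intervals did not overlap.

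The 5 densest windows of shared sites, each 1 kb long and all on the minus strand of mm9, lay on chromosomes 14, 1, 13, 19 and 7. The window on chromosome 14, from 52818058 to 52819057, held 4 shared sites out of 7 in replicate 1 and 5 in replicate 2, with their central bases between 52818060 and 52818133. On chromosome 1, from 135517571 to 135518570, all 4 sites of replicate 1 were among the 5 of replicate 2. On chromosome 13, from 29043475 to 29044474, the 4 sites of replicate 2 were among the 5 of replicate 1, and all 4 lay between 29043477 and 29043504. On chromosome 19, from 24550935 to 24551934, 4 shared sites lay between 24550937 and 24550955, with 4 sites in replicate 1 and 5 in replicate 2. The window on chromosome 7, from 125278483 to 125279482, held 3 shared sites, the whole of the replicate 1 set there, among 6 in replicate 2. Whether these windows fall in exons, introns or untranslated regions was not analysed here.

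**Figure D2:**
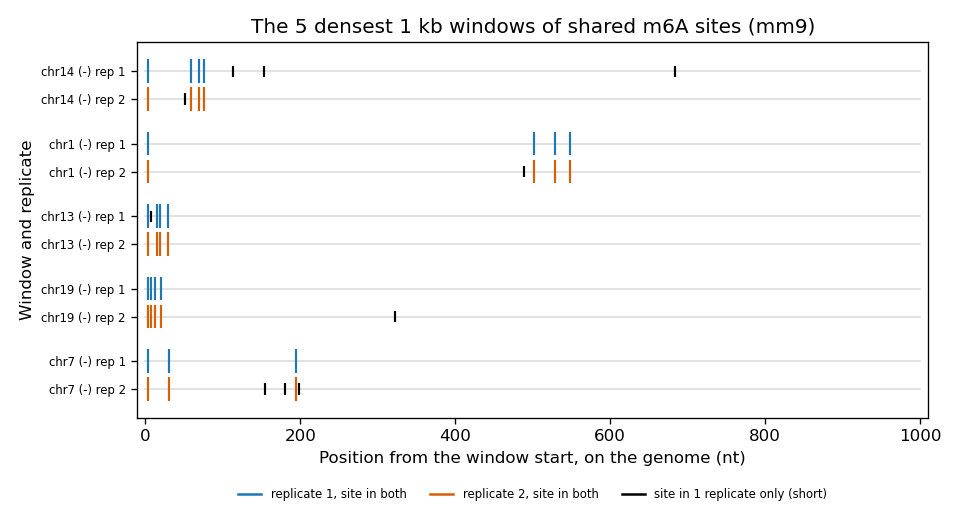
Positions of m6A sites in the 5 densest 1 kb windows of shared sites, in nt from the window start on the genome; long coloured ticks are sites found in both replicates and short black ticks sites found in 1 replicate only. In the windows on chromosomes 13 and 19 the 4 shared sites sit close together; each window begins at a shared site by construction.

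The distance between neighbouring sites was bounded below. On the same strand, no pair of distinct sites lay 1 to 3 nt apart, in either replicate or between replicates. At 4 nt there were 20 pairs in replicate 1, 17 in replicate 2 and 33 between replicates. Distances of 4 to 10 nt occurred 109 times in replicate 1, 117 times in replicate 2 and 200 times between replicates. At that rate per nucleotide, 46.7, 50.1 and 85.7 pairs would have lain 1 to 3 nt apart. Among sites found in 1 replicate only, 84 pairs between replicates were 4 to 10 nt apart and 0 were 1 to 3 nt apart, where 36.0 were expected at the same rate.

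**Figure D3:**
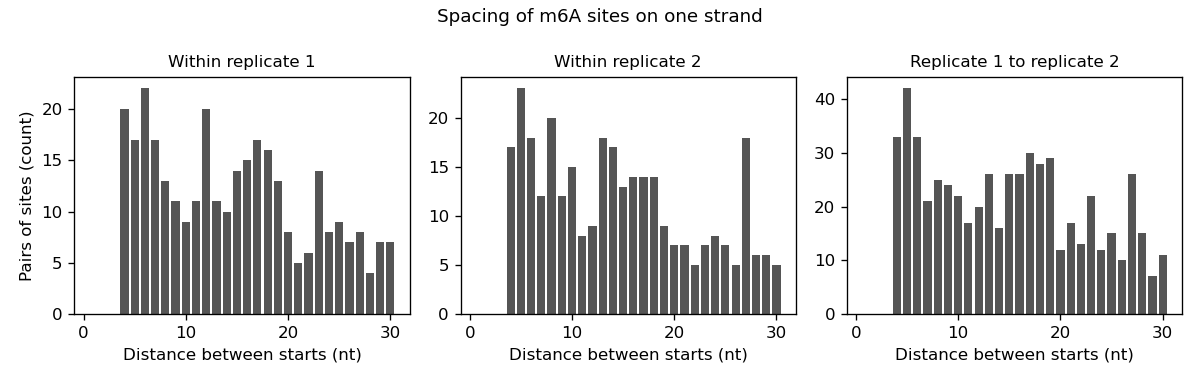
Number of pairs of distinct same-strand m6A sites at each distance from 1 to 30 nt between interval starts, within each replicate and between replicates. No pair lies 1 to 3 nt apart, and at 4 nt there are 20, 17 and 33 pairs.

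Positions that a list repeated on several lines recurred more often in the other replicate. Replicate 1 listed 482 positions more than once (6.87%) and replicate 2 listed 465 (6.47%), with at most 5 lines for a position. Of the positions on 1 line, 22.6% of replicate 1 (21.6 to 23.6%) and 22.1% of replicate 2 (21.1 to 23.1%) were shared. The shares rose to 40.0% (35.6 to 44.7%) and 39.7% (35.1 to 44.4%) for positions on 2 lines, and to 75.0% (59.8 to 85.8%) and 84.6% (70.3 to 92.8%) for positions on 3 or more. The intervals of these 3 classes did not overlap in either replicate. Both replicates draw on the same 1685 shared positions, so their results are not independent. The class of 3 or more lines held only 40 positions in replicate 1 and 39 in replicate 2. All 6 positions on 4 or more lines in replicate 1, and all 8 in replicate 2, were shared. Among the 1685 shared positions, 117 were repeated in both lists, where 24.8 were expected if repetition in one list were unrelated to that in the other (odds ratio 21.2, 95% interval 14.8 to 30.7).

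**Figure D4:**
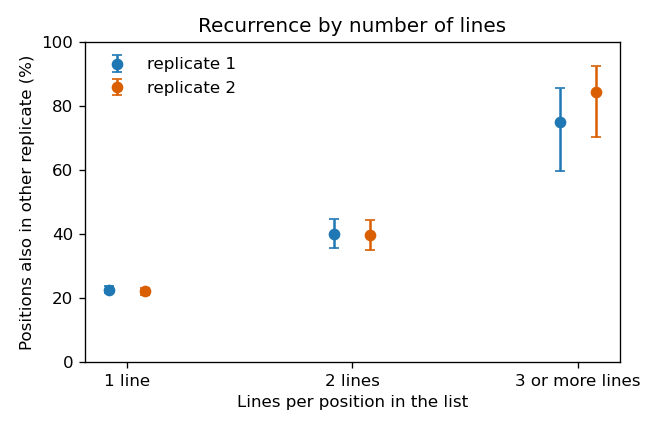
Percentage of positions also found in the other replicate, by the number of lines on which a list gave the position; dots are single replicates and bars 95% Wilson intervals. The share rises from 22.6% and 22.1% at 1 line to 75.0% and 84.6% at 3 or more.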

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

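Of the tests in this part, the comparison of line numbers between lists and the check on merged windows were chosen after the results were seen.

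The lists repeated 482 positions of replicate 1 and 465 of replicate 2 on more than 1 line, a property that no other field explains, and repeated positions recurred more often. Lines duplicated by accident while each file was written separately would fall on unrelated positions in the lists. The odds ratio of 21.2 for repetition in both lists argues against that. Duplication in a step common to both lists was not tested, because the steps that made the lists are not given. A line for each overlapping annotation record would give a shared position equal numbers of lines in both lists. However, 69.2% of the 292 shared positions with several lines in either list had different numbers (63.7 to 74.2%). Most of these were repeated in 1 list only and so differ by definition: 90 in replicate 1 only and 85 in replicate 2 only. The other 117 of the 292 were repeated in both lists. Crowding of called sites within 1 kb on the same strand did not account for the whole difference. Within strata of the number of such neighbours, the Mantel-Haenszel odds ratio of recurrence for repeated positions was 2.58 in replicate 1 (2.14 to 3.12). In replicate 2 it was 2.69 (2.22 to 3.26). No site was assigned to a transcript, so crowding over whole transcripts was not tested. A hypothesis left open is that a line stands for a separate piece of evidence, such as a mutated or truncated cDNA position near 1 methylated base, which no value in the lists tests, and the single group gives no biological contrast.

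The replicates shared 24.0% and 23.5% of their sites. Allowing 5 nt raised the matches by a factor of 1.02 in the replicate where it raised them more. No pair of sites between replicates lay 1 to 3 nt apart. If the calls were filtered by motif or spacing, the small rise was fixed in advance. It therefore cannot exclude displacement of called positions by a few nucleotides. Scatter over the genome without regard to transcripts does not account for the unmatched sites as a whole. They had a same-strand neighbour in the other replicate at least 43.2 times as often as an opposite-strand one. Such a same-strand neighbour within 1 kb was present for 34.0% of the unmatched sites of replicate 1 and 31.9% of those of replicate 2. The ratio does not bear on the rest. Displacement under a filter on motif or spacing stays open, as does scatter for the unmatched sites without a same-strand neighbour. Other explanations that stay open, not tested for want of read counts, are incomplete sampling of a larger set of methylated positions, and background calls inside expressed transcripts. No biological explanation was tested.

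Sites on 1 strand were never 1 to 3 nt apart. Placement without any rule on position or spacing is excluded, as the rate of such distances between replicates was at most 0.0350 of that at 4 to 10 nt (upper 95% limit). Merging of overlapping windows within each list is excluded too: the limit was 0.0832 among sites found in 1 replicate only, and pairs 4 nt apart, whose intervals overlap, were present. A minimum spacing set on the calls of both replicates together would leave the same gap without a sequence rule. It could not be tested, because the site caller and its filters are not given. The gap is consistent with every interval being an instance of DRACH, the usual m6A context (D is A, G or U, R is A or G, H is A, C or U), since a second such motif cannot start 1 to 3 nt after a first but can start 4 nt after it. This remains a hypothesis, because no sequence was read, and it does not tell a filter on the motif by the submitters from a preference of the methylation itself.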

How the results depend on the processing

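Of 22 alternative values, 9 stayed within the limits of the reported value (1.5 times for counts, 1 SD between replicates for shares), 13 moved and 0 reversed. Counts and shares carry no sign, so the lack of reversals says nothing on their stability. The 22 values leave out 8 shares of single replicates, which always lie within 1 SD of a mean of 2. Those using only positions on 2 or more lines, or groups of sites, were chosen after seeing the data. Counting every line gave 7623 sites per replicate and merging sites within 5 nt gave 7062. The 1685 shared sites were also found with 1 nt allowed or with strand ignored, and became 1724 within 5 nt and 2129 within 50 nt. Replicates 1 and 2 alone had 7019 and 7182 sites, 15.1% and 12.7% of sites with a neighbour within 100 nt, 34.8% and 33.0% within 1 kb, 3.177% and 3.202% on the X chromosome, and 8.86% and 8.65% on chromosome 11. The share of sites with a same-strand neighbour, 13.9% within 100 nt, was 9.98% within 50 nt and 19.1% within 200 nt. It was 7.48% within 100 nt and 14.6% within 1 kb among shared sites only, sets with fewer sites and hence fewer neighbours by construction. With only positions on 2 or more lines, the sites numbered 473.5 per replicate, 117 were shared, and 2.21% had a neighbour within 100 nt and 4.71% within 1 kb, a mean of 7.26% in replicate 1 (35 of 482) and 2.15% in replicate 2 (10 of 465). Only such positions counted as neighbours here, so these neighbour shares are also low by construction. The X chromosome's share of 3.19% became 2.49% among shared sites, 3.11% with groups as the unit and 3.07% among positions on 2 or more lines; chromosome 11's share of 8.75% became 8.55% among shared sites and 7.90% among positions on 2 or more lines. The limit for these shares is narrow, because the replicates differed so little, and no alternative changed which of the 2 chromosomes had the larger share. Alternatives that need genes, sequence or a score were not run. No paired analysis was possible because there is only 1 group.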

Other observations

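The 5 intervals of 1 Mb with the most sites in both replicates together are given here, and were chosen after their values were seen. Chromosome 11 from 69000001 to 70000000 had 31 sites in replicate 1 and 34 in replicate 2. Adjoining intervals of chromosome 17, from 34000001 to 35000000 and from 35000001 to 36000000, had 32 and 33 sites in replicate 1 and 29 and 31 in replicate 2. Chromosome 7 from 52000001 to 53000000 had 30 and 25 sites, and chromosome 5 from 23000001 to 24000000 had 23 and 29. Across 2636 intervals of 1 Mb, which are not independent replicates, site counts of the 2 replicates had a Pearson correlation of 0.887 and a Spearman correlation of 0.845. With the shared positions left out, these were 0.810 and 0.760. Intervals without a site in either replicate, 915 with all sites and 975 with the shared positions left out, count in these correlations.

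The largest group of sites lay on the plus strand of chromosome 17. Replicate 1 had 15 sites from 23952380 to 23955654, and replicate 2 had 9 sites in that stretch, of which 2 were at the same position. Replicate 2 had 2 further groups of 9 sites. One, on the minus strand of chromosome 5 from 92482098 to 92483869, held 4 replicate 1 sites, all at shared positions. The other, on the plus strand of chromosome 19 from 40986447 to 40988813, held 2 replicate 1 sites and no shared position. The position with the most lines in both lists, on the plus strand of chromosome 6 from 126354652 to 126354656, had 5 lines in each.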
